A study of Homo sapiens with 4 samples.

How the data were processed

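RNA was measured in 4 samples of human erythroblasts, the nucleated precursors of red cells. Per the labels' protocols, primary human CD34-positive hematopoietic progenitors were transduced with lentiviral vectors carrying a short hairpin RNA (shRNA) against either LacZ, a bacterial gene that human cells lack, or NCOA4; the protocol text leaves the name of the second target blank, and the sample titles and design text give it as NCOA4. Transduction was done with 2 µg/mL polybrene, selection in 1 µg/mL puromycin began 24 hours after transduction and lasted 2 days, and cells were harvested on day 14 of erythroid differentiation. Total RNA was prepared with an Illumina TruSeq RNA kit for paired-end mRNA sequencing, per the labels' protocols. The labels give 2 samples per group and do not say whether they came from separate cultures or donors, so p-values here measure only the spread between these samples, which may be technical. The number and sequence of the hairpins are not given in the sources used here.

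The submitters' processing notes name TopHat2 as aligner and HTSeq as read counter, without versions, and list the genome builds GRCh37.p11, hg19 and NCBIM37. The last is the name of a mouse build, and the notes do not say which build served which step. The strand setting and the treatment of reads that map to several places are not given in the sources used here. Genes that overlap, antisense genes and near-identical copies are therefore uncertain, among them HBA1 and HBA2, HBG1 and HBG2, RHD and RHCE, and genes with processed pseudogenes such as FTH1, FTL and the ribosomal protein genes. The authors deposited 1 table with a whole-number count of reads per gene and library for 57232 Ensembl genes, with no normalization applied to these counts per the file headers. The same table holds the authors' ratio of NCOA4 knockdown to LacZ control, and the authors' p-value and adjusted p-value for each gene, whose test is not named in the file headers. The deposited ratio and p-values were used only where the text names the authors' deposited table. A further 4 per-sample columns of normalized values, the group means and a log2 column were not used. The count columns name the group and a letter rather than the replicate number of the labels, so each column was taken as a library of its group with no number, and libraries are told apart below by their total counts.

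The total count per library was 33776636 and 27078906 in the controls and 37393161 and 25342754 in the knockdown, so that 1 count was worth 0.0296, 0.0370, 0.0268 and 0.0395 counts-per-million (CPM). XIST and Y-linked genes (482 in all) were left out of every step, because the cells were primary human cells. The remaining counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default settings (16203 genes), libraries were scaled with TMM factors, and groups were compared with the quasi-likelihood test (glmQLFit and glmQLFTest) in a model with the group alone. The test was two-sided with Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p under 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. The fit had 2 residual degrees of freedom and a prior of 10.6, and the common biological coefficient of variation was 4.92%. Log2 CPM values for gene lists and principal components used a prior count of 2. Means are given with the SD of the 2 libraries of a group, in TMM-scaled CPM.

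A set of 27 gene lists (771 entries, of which 712 were tested) was fixed from textbook knowledge before the data were examined, including markers of 5 other blood lineages. Lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry, which asks whether the genes of a list move one way on balance without comparing them with other genes. The genes named in the text follow a rule set at the same time. It takes a fixed set of genes whatever their result, among them NCOA4, FTH1, FTL, TFRC, ALAS2, HBA1, HBA2, HBB, HBG1, HBG2, SLC4A1, GATA1, KLF1, KIT, THRA and THRB. It adds the 8 largest rises and 8 largest falls among called genes that are protein-coding or carry an approved symbol, have a mean log2 CPM of at least 3 and do not overlap between groups, and for each list the 2 members with the smallest p in each direction. A further 3 genes that meet the rule are not reported here. Further genes named as examples in the text were chosen after their values were seen.

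The edgeR and camera steps were tested on simulated counts with the means and library sizes of this comparison of NCOA4 knockdown with control, over 16171 genes. Of the genes changed 1.25-fold, 34.7% of 49 were called; the shares were 72.0% of 50 at 1.5-fold, 81.2% of 48 at 2-fold and 98.0% of 49 at 4-fold, and 5.26% of the calls were false. A list shifted by 0.4 on the log2 scale was recovered with the preset correlation and not with an estimated one, and 0 of the unshifted lists were called. The simulated genes were drawn independently of each other, so the simulation cannot tell which correlation setting holds for the real lists. Far fewer genes were changed in it than were called in the data, so its share of false calls need not carry over. Alternatives were other scalings (RLE size factors, library size alone, globin genes left out), no count filter, a filter of at least 10 CPM in 2 libraries, DESeq2 1.42.0, limma voom, and leaving out each library in turn. A covariate for library size, a block by the letter of the count column and a count restricted to abundant genes were added after the data were examined. A GENCODE annotation of a later build than the one in the notes was used for gene types, transcript lengths and GC content and for leaving out Y-linked genes; 51367 of the table's identifiers matched it, and no coordinates are given because the builds differ. The principal components, correlations and shares of counts are values without a test.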

Results

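NCOA4 is the cargo receptor that carries ferritin, the iron storage protein, to the lysosome, and it was first described as a coactivator of nuclear receptors. The series asked how gene expression in human erythroblasts differs when NCOA4 is knocked down. Counts of mRNA sequencing reads per gene were available for 4 libraries from cells harvested on day 14 of erythroid differentiation, 2 with a LacZ control shRNA and 2 with an NCOA4 shRNA. The deeper control library held 33776636 counts and the shallower 27078906, and the deeper knockdown library held 37393161 and the shallower 25342754.

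NCOA4 (ENSG00000138293) was lower in both knockdown libraries. Its level was 1480 ± 28.1 CPM (counts-per-million; SD, n = 2) in the control and 675 ± 8.18 CPM (SD, n = 2) in the knockdown, a log2 fold change of -1.13 (SE 0.058). This was 2.19-fold lower, with an edgeR adjusted p of 1.65e-08. In the authors' deposited table the ratio of knockdown to control for NCOA4 was 0.458, with an adjusted p of 3.53e-71. The ferritin subunit mRNAs did not pass the threshold: FTH1 had a log2 fold change of -0.04 (SE 0.086, edgeR adjusted p = 0.707) and FTL of 0.06 (SE 0.078, edgeR adjusted p = 0.597). The sign of FTH1 turned with library size alone and without the shallower library of either group, and that of FTL turned without the deeper control library (-0.03). Without the shallower control library FTL passed the threshold (0.16, edgeR adjusted p = 0.0363; range over its alternatives 0.0363 to 0.89).

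Across the transcriptome, 3555 genes were higher and 3908 lower in the knockdown at an edgeR adjusted p under 0.05, out of 16203 tested. Most rises were small, with 3084 of the 3555 under 1.5-fold, while 1735 of the 3908 falls were under 1.5-fold. Changes of at least 2-fold went mostly down, with 111 genes higher and 1148 lower. In all but 3 of the 7463 called genes, both knockdown libraries lay on the same side of both control libraries, which a call with 2 libraries per group nearly requires. Such separation was seen in 72.1% of all genes tested, where chance gives 33.3% for a single gene. Genes move together, so any difference shared by the libraries of a group can raise this share, whatever its source. More genes rose than fell with library size alone as the scaling (4105 against 3465) and without a count filter (3843 against 3784), and also among genes with a mean log2 CPM of at least 5, with 1997 genes higher in NCOA4 kd and 1485 genes lower in NCOA4 kd. Among changes of at least 2-fold falls outnumbered rises in every alternative tried, although without the deeper knockdown library 229 genes rose that far. All 5243 genes that were called in the authors' deposited table at an adjusted p under 0.05 and tested here were called here in the same direction. The rest of the 7463 genes called here, HBA1, HBA2 and THRB among them, were not called in that table. Both sets of calls rest on the same 4 libraries. The first principal component held 73.3% of the variance and separated the groups, and the second separated mainly the knockdown libraries from each other. Spearman correlations across genes were 0.997 and 0.995 within groups and 0.982 to 0.985 between them. Libraries of a group differed by more than sampling noise, with a mean chi-square per gene of 9.28 in the control and 6.56 in the knockdown.

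**Figure D1:**
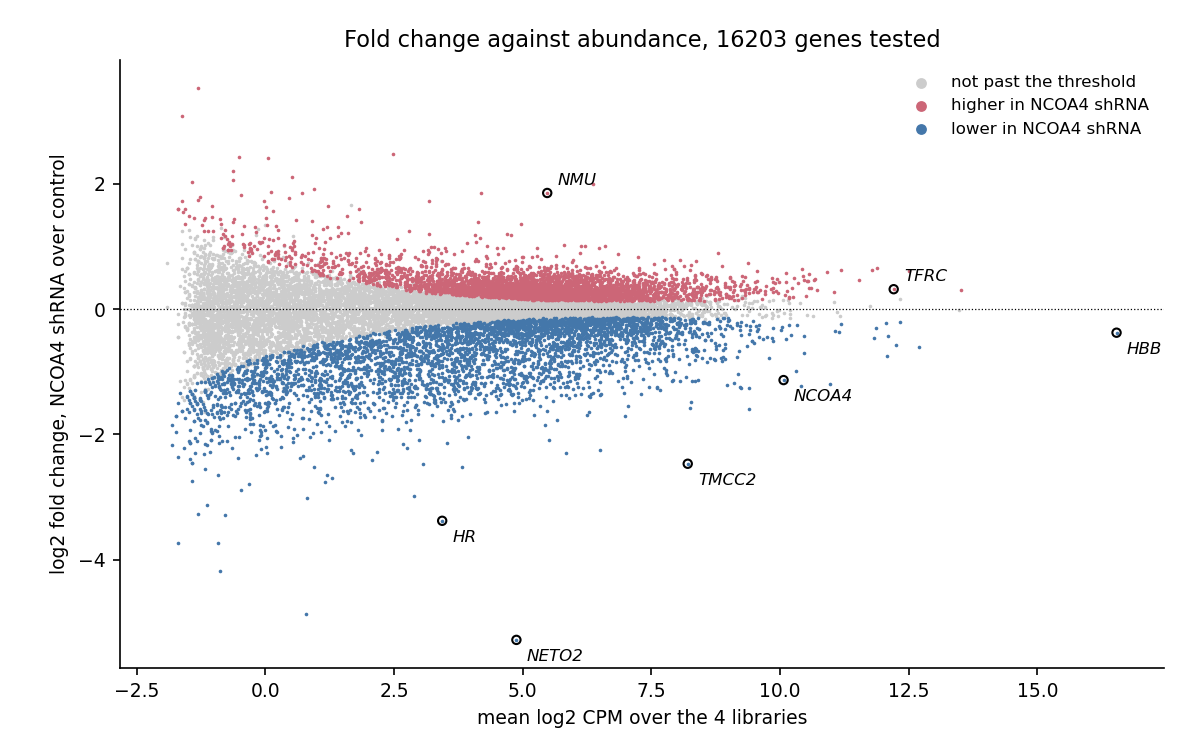
Log2 fold change of NCOA4 shRNA over LacZ shRNA control (vertical axis) against the mean log2 CPM of the 4 libraries (horizontal axis) for the 16203 genes tested, coloured by direction where the edgeR adjusted p was under 0.05. Large falls outnumber large rises (1148 against 111 at 2-fold or more), and NETO2, HR and TMCC2 stand lowest among the labelled genes.

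The largest fall among the genes named by rule was that of NETO2, a transmembrane protein known as an auxiliary subunit of kainate receptors, which went from 57.6 ± 0.513 to 1.51 ± 0.263 CPM (SD, n = 2 each; log2 fold change -5.28, SE 0.0995, edgeR adjusted p = 6.23e-12). HR, a nuclear receptor corepressor and textbook target of thyroid hormone, followed with -3.38 (SE 0.12). TMCC2, an abundant erythroid transcript, fell from 501 ± 10.9 to 90.7 ± 0.986 CPM (SD, n = 2 each; log2 fold change -2.47, SE 0.053, edgeR adjusted p = 1.64e-11). The other large falls were TCN1 (-2.52), a vitamin B12 binding protein of granulocytes, the chemokine CCL2 (-2.48), the prostaglandin-degrading enzyme HPGD (-2.30), IFIT1B (-2.25) and the hexokinase HK3 (-2.14) on the log2 scale. The largest rises under the same rule were smaller. The neuropeptide gene NMU rose from 19.2 ± 0.277 to 69.5 ± 0.71 CPM (SD, n = 2 each; log2 fold change 1.85, SE 0.058, edgeR adjusted p = 6.28e-10), and FAM178B rose by 1.73, the monocarboxylate transporter family member SLC16A9 by 1.37, the mitochondrial folate enzyme MTHFD1L by 1.19, the glycosyltransferase B3GALNT1 by 1.19, the metallothionein MT1G by 1.18 and the exchange factor VAV2 by 1.18 on the log2 scale. RPL13P12, a ribosomal protein pseudogene, also met the rule (1.38, SE 0.37), but the size of its rise rested on the shallower knockdown library. Without that library the log2 fold change was 0.37. Its call was kept in 12 of 13 alternatives and lost in DESeq2 (adjusted p = 0.158).

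Markers of other blood lineages were lower in the knockdown, in each of the 5 lists fixed for them. Of 70 marker genes tested, 62 fell, 0 rose and 8 did not pass the threshold by edgeR. Megakaryocyte and platelet genes fell in 18 of 19 (median log2 fold change -1.29, camera adjusted p = 1.14e-10; adjusted p = 0.211 with an estimated correlation), including NRGN (-1.33, SE 0.052) and RAB27B (-1.36, SE 0.054). Mast cell, basophil and eosinophil genes fell in 15 of 16 (16 adjusted over the list alone; median -1.22, camera adjusted p = 1.14e-08; adjusted p = 0.211 with an estimated correlation). Their examples were FCER1A, a chain of the IgE receptor (-1.71, SE 0.056), and HPGD, and their most abundant member CLC, the Charcot-Leyden crystal protein, fell by 1.23 on the log2 scale from 1891 CPM in the control. Neutrophil and granulocyte precursor genes fell in 11 of 13 (12 adjusted over the list alone; median -1.10, camera adjusted p = 2.28e-06; adjusted p = 0.211 with an estimated correlation), among them the granule proteins MPO (-1.07, SE 0.049) and ELANE (-1.43, SE 0.078). Monocyte and macrophage genes fell in 14 of 16 (median -1.08, camera adjusted p = 4.46e-05; adjusted p = 0.211 with an estimated correlation), including the integrins ITGAX (-1.26, SE 0.064) and ITGAM (-1.07, SE 0.057). Lymphoid genes were scarce: 6 of 21 could be tested and 4 fell (median -1.49, camera adjusted p = 0.00992; adjusted p = 0.214 with an estimated correlation), including IL7R (-1.86, SE 0.20) and NKG7 (-1.79, SE 0.24). The lymphoid call was lost without a count filter (median -0.44, adjusted p = 0.0888; range over its alternatives 0.000726 to 0.214), and the median was -0.93 without the deeper knockdown library.

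**Figure D2:**
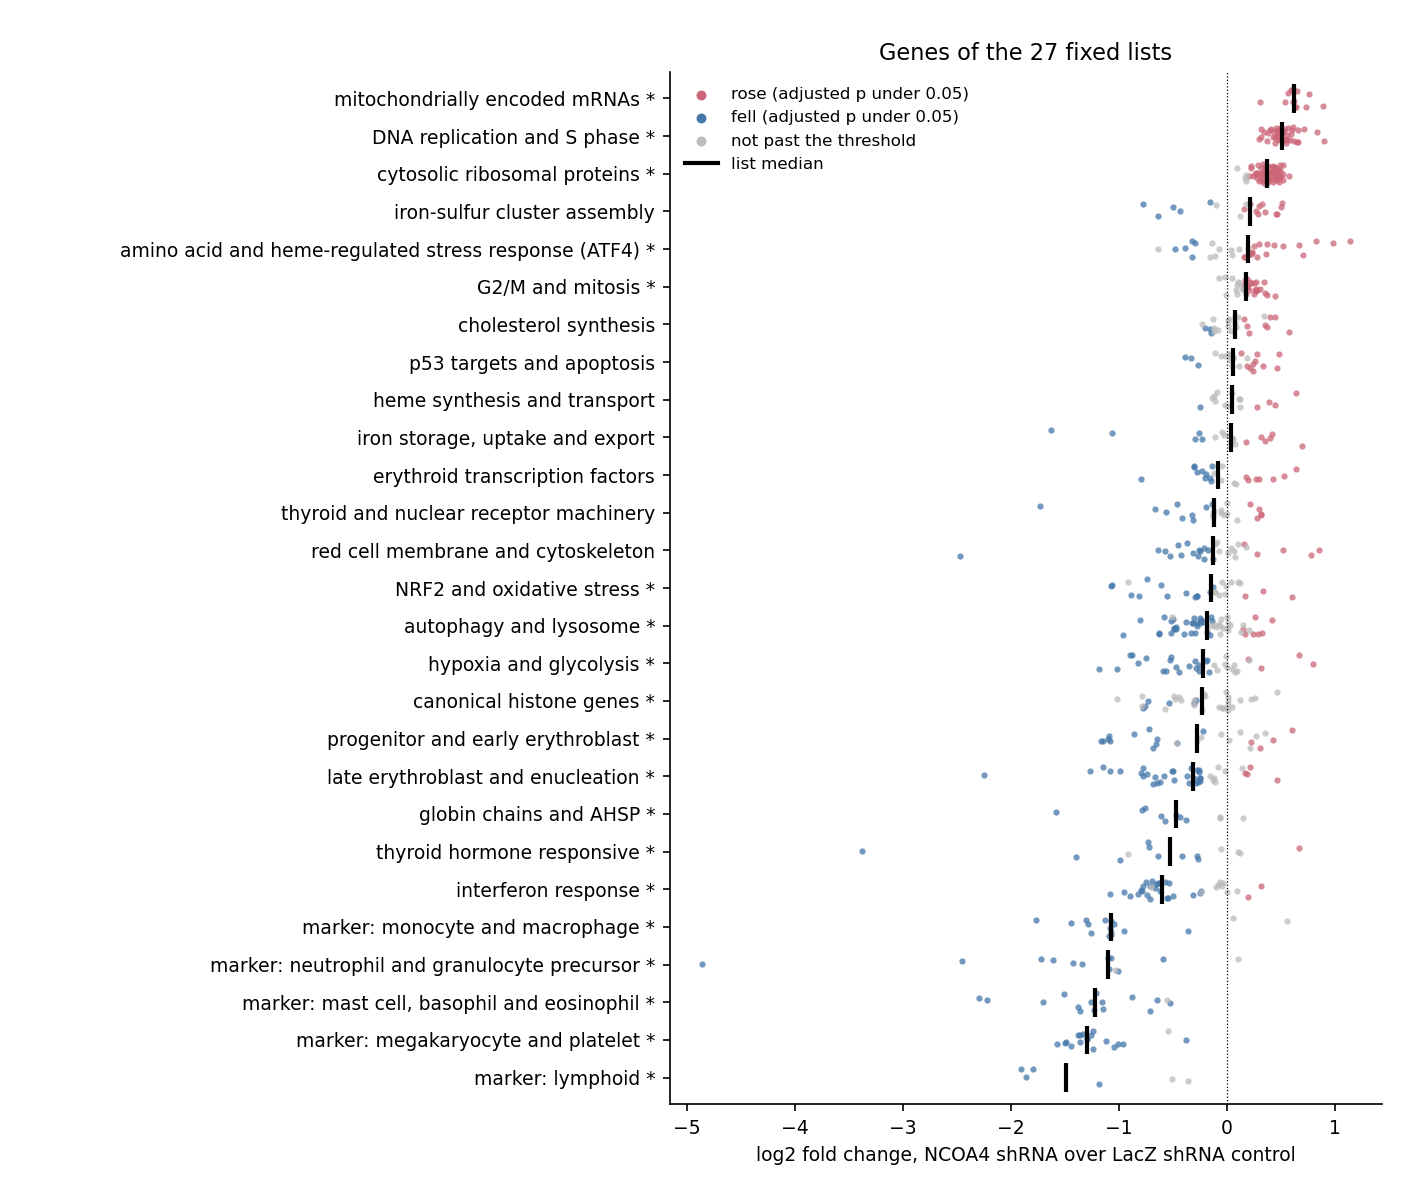
Log2 fold change of NCOA4 shRNA over LacZ shRNA control (horizontal axis) for each tested member of the 27 fixed lists (rows, ordered by median), with points coloured by the edgeR call and black bars at the list median. Asterisks mark the 19 lists with a camera adjusted p under 0.05 at the preset correlation; DNA replication genes had a median of 0.51 and megakaryocyte markers of -1.29.

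With an estimated correlation, 0 of the 27 lists passed an adjusted p under 0.05 in camera, against 4 at an unadjusted p under 0.05, while 22 passed in fry and 19 with the preset correlation. Fry passed the heme, iron-sulfur, red cell membrane, nuclear receptor and p53 lists as well and did not pass the mitochondrial mRNA and histone lists. A difference in cell composition or cell stage between the groups was not tested for any list below, and 62 of 70 markers of other lineages fell in the same libraries. Counts adjusted over the list alone equalled those over all genes tested in 16 lists and are given beside the others.

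Globin mRNAs were lower in the knockdown, while 10 of 15 heme synthesis and transport genes did not pass the threshold. These lists were not tested against each other. Markers of other lineages fell in the same libraries (62 of 70) and mitochondrially encoded transcripts took a larger share of counts (4.24 ± 0.598% in the control and 5.61 ± 0.409% in the knockdown; SD, n = 2 each). Fewer cells of other lineages would not by themselves lower erythroid transcripts such as the globins, and a difference in cell stage was not tested. Of 11 globin and globin chaperone genes, 8 fell, 0 rose and 3 did not pass (median log2 fold change -0.47, camera adjusted p = 0.0161; adjusted p = 0.42 with an estimated correlation). The embryonic globin HBE1 had the largest fall, from 455 ± 0.28 to 152 ± 3.89 CPM (SD, n = 2 each; -1.58, SE 0.051). The fetal globins, whose copies share reads, fell by 0.79 (HBG1, SE 0.12) and 0.76 (HBG2, SE 0.11) on the log2 scale, and by 0.76 (SE 0.11, edgeR adjusted p = 0.0001) when counted together. The adult alpha-globins fell by 0.57 (HBA1, SE 0.15) and 0.61 (HBA2, SE 0.15), and by 0.59 (SE 0.15, edgeR adjusted p = 0.00606) together. HBB, the adult beta-globin, took 10.5 ± 0.679% of counts in the control and 8.39 ± 0.522% in the knockdown (SD, n = 2 each), a log2 fold change of -0.38 (SE 0.12, edgeR adjusted p = 0.018). Without the shallower control library HBA1 was at -0.26 and HBA2 at -0.32, and the call of the list was lost (adjusted p over its alternatives 0.00132 to 0.42). The alpha-globin calls were lost in DESeq2 and that of HBB without the deeper knockdown library, under the filter of 10 CPM and with a covariate for library size (adjusted p over the alternatives 1.06e-23 to 0.179 for HBA1, 3.67e-28 to 0.122 for HBA2 and 1.51e-13 to 0.158 for HBB).

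Among 15 heme synthesis and transport genes, 4 rose, 1 fell and 10 did not pass (median 0.05, from 0.016 to 0.070 with a library left out, camera adjusted p = 0.286, fry upward with an adjusted p of 0.0351). TMEM14C, a porphyrinogen importer of the mitochondrion, rose by 0.64 (SE 0.051) and UROS, uroporphyrinogen III synthase, by 0.45 (SE 0.049) on the log2 scale, and the porphyrin transporter ABCB6 fell by 0.25 (SE 0.054). ALAS2, the erythroid enzyme of the committed step, had a log2 fold change of -0.11 (SE 0.064, edgeR adjusted p = 0.188). Of 19 genes of iron storage, uptake and export, 6 rose, 5 fell and 8 did not pass (median 0.04, from 0.017 to 0.066 with a library left out, mean -0.06, camera adjusted p = 0.782 in the upward direction, fry downward with an adjusted p of 0.0664). The transferrin receptor TFRC rose from 4215 ± 14.2 to 5254 ± 70.7 CPM (SD, n = 2 each; 0.32, SE 0.071, edgeR adjusted p = 0.00257), the ferrireductase STEAP3 by 0.69 (SE 0.05) and TFR2 by 0.42 (SE 0.054) on the log2 scale. Heme oxygenase HMOX1 (-1.06, SE 0.055) and the ferroxidase HEPH (-1.63, SE 0.09) fell. Iron-sulfur cluster assembly genes went both ways, with 11 higher, 5 lower and 3 not past the threshold of 19 (median 0.21, camera adjusted p = 0.0868). Ferredoxin reductase FDXR rose (0.46, SE 0.052), and IBA57 (-0.77, SE 0.056) and ISCA1 (-0.43, SE 0.05) fell.

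Genes of late erythroblasts and enucleation were mostly lower, in the same libraries in which 62 of 70 markers of other lineages fell. Fewer cells of other lineages would not by themselves lower transcripts made mainly by erythroid cells. Whether a difference in cell stage lowered these late genes was not tested. Of 40 tested, 29 fell, 4 rose and 7 did not pass (32 fell and 5 rose adjusted over the list alone; median log2 fold change -0.32, camera adjusted p = 6.15e-07; adjusted p = 0.211 with an estimated correlation). TRIM58, a ubiquitin ligase of enucleating erythroblasts, fell from 328 ± 7.22 to 148 ± 4.7 CPM (SD, n = 2 each; -1.15, SE 0.051), IFIT1B fell as given above, and further falls were those of the nuclear exportin XPO7 (-1.26, SE 0.06), the ubiquitin conjugating enzyme UBE2H (-1.08, SE 0.052) and the mitophagy receptor BNIP3L (-0.58, SE 0.054). Carbonic anhydrase CA1 (0.46, SE 0.081) and cyclin CCND3 (0.21, SE 0.058) rose. Red cell membrane genes divided into 15 lower, 5 higher and 9 not past the threshold of 29 (median -0.13, camera adjusted p = 0.111). TMCC2 and SEMA7A (-0.64, SE 0.053) fell, and the water channel AQP1 (0.78, SE 0.049) and BCAM, the Lutheran antigen (0.85, SE 0.054), rose. Band 3, SLC4A1, was at -0.21 (SE 0.072, edgeR adjusted p = 0.0299), a call that was lost with either knockdown library left out, with library size alone and with a covariate for library size (adjusted p over its alternatives 0.000147 to 0.169).

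Erythroid transcription factors went both ways, with 7 higher, 10 lower and 5 not past the threshold of 22 (11 lower adjusted over the list alone; median -0.08, camera adjusted p = 0.795). LMO2 (0.64, SE 0.049) and its partner LDB1 (0.53, SE 0.067) rose, and FOXO3, which drives late erythroid genes (-0.80, SE 0.057), and NFE2L2 (-0.30, SE 0.052) fell. GATA1, the master erythroid factor, was at 0.09 (SE 0.052, edgeR adjusted p = 0.199; 0.13 and past the threshold without the shallower control library, adjusted p over its alternatives 0.0418 to 0.494) and KLF1 at 0.07 (SE 0.055, edgeR adjusted p = 0.334). Progenitor and early erythroblast genes fell in 12 of 25, with 4 higher and 9 not past the threshold (13 lower adjusted over the list alone; median -0.27, camera adjusted p = 0.022; adjusted p = 0.218 with an estimated correlation). The members that fell included GATA2 (-1.15, SE 0.05), TESPA1 (-1.09, SE 0.056) and the stem cell factor receptor KIT (-0.65, SE 0.048). GATA2 and KIT also stand in the mast cell list, whose median was -1.22. MYC (0.61, SE 0.06) and the nucleolar protein NPM1 (0.43, SE 0.056) rose. This list's call was lost without the shallower control library (adjusted p = 0.0587; range over its alternatives 0.00226 to 0.218), and its median was -0.59 under the filter of 10 CPM and -0.43 without the deeper control library.

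Genes known to respond to thyroid hormone were lower, with 9 of 14 down, 1 up and 4 not past the threshold (10 lower adjusted over the list alone; median log2 fold change -0.52, camera adjusted p = 0.00481; adjusted p = 0.324 with an estimated correlation). HR fell from 19.9 ± 1.02 to 1.94 ± 0.264 CPM (SD, n = 2 each; edgeR adjusted p = 1.37e-09) and the transcription factor KLF9 from 63.3 ± 0.58 to 24.0 ± 0.377 CPM (SD, n = 2 each; -1.40, SE 0.057). The thyroid hormone transporter SLC16A10 rose at a low level, from 2.74 ± 0.0577 to 4.38 ± 0.257 CPM (SD, n = 2 each; 0.67, SE 0.16). The lists of other-lineage markers fell in the same libraries, with medians from -1.49 to -1.08, and whether a difference in cell composition lowered the thyroid hormone list was not tested. The median of the list was -0.26 without a count filter. The receptors themselves moved little: THRA was at -0.13 (SE 0.058, edgeR adjusted p = 0.0912; past the threshold under the filter of 10 CPM, adjusted p over its alternatives 0.0298 to 0.444) and THRB at 0.28 (SE 0.10, edgeR adjusted p = 0.0419) from 7.82 CPM in the control, and the THRB call was lost without the deeper control library, without the deeper knockdown library and in DESeq2 (adjusted p over its alternatives 0.0198 to 0.248). Of 24 genes of nuclear receptors and their cofactors, 9 fell, 5 rose and 10 did not pass (median -0.12, camera adjusted p = 0.18). The acetyltransferase EP300 (-0.66, SE 0.058) and NCOA7 (-0.42, SE 0.056) fell, and HDAC3 (0.32, SE 0.054) and MED1 (0.29, SE 0.062) rose.

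Autophagy and lysosome genes fell in 29 of 53, with 7 higher and 17 not past the threshold (10 higher adjusted over the list alone; median log2 fold change -0.19, camera adjusted p = 0.00364; adjusted p = 0.211 with an estimated correlation). GABARAPL1, which binds the autophagosome membrane, fell from 115 ± 0.98 to 59.0 ± 0.757 CPM (SD, n = 2 each; -0.96, SE 0.051) and ATG14 by 0.81 (SE 0.058) on the log2 scale, and PIK3R4 (0.33, SE 0.055) and ATG3 (0.25, SE 0.049) rose. Genes of the NRF2 oxidative stress program fell in 13 of 26, with 3 higher and 10 not past the threshold (median -0.14, camera adjusted p = 0.0125; adjusted p = 0.213 with an estimated correlation). HMOX1 and AKR1C1 (-1.08, SE 0.061) fell, and PRDX2 (0.33, SE 0.057) and PIR (0.60, SE 0.11) rose. Interferon response genes fell in 25 of 36, with 2 higher and 9 not past the threshold (26 lower adjusted over the list alone; median -0.60, camera adjusted p = 2.92e-06; adjusted p = 0.211 with an estimated correlation). SAMD9 (-0.90, SE 0.05) and RSAD2 (-0.80, SE 0.056) had the smallest p among the falls, and HERC6 (0.32, SE 0.071) and HERC5 (0.19, SE 0.07) were the rises. The HERC5 call was lost in DESeq2, under the stricter filter, and without the shallower control library or the deeper knockdown library (0.10 without the last; adjusted p over its alternatives 0.00859 to 0.401). Hypoxia and glycolysis genes fell in 20 of 34, with 4 higher and 10 not past the threshold (5 higher adjusted over the list alone; median -0.22, camera adjusted p = 0.00665; adjusted p = 0.211 with an estimated correlation). The pyruvate kinase PKM of most tissues fell by 1.18 (SE 0.055) on the log2 scale while PKLR, the kinase of liver and red cells, rose by 0.80 (SE 0.057). The glucose transporter SLC2A3 fell (-1.02, SE 0.057) and the phosphofructokinase PFKM rose (0.67, SE 0.052). Across the 5 lists of other lineages, markers fell in the same libraries with medians from -1.49 to -1.08.

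Genes of DNA replication rose together, in the same libraries in which 62 of 70 markers of other lineages fell. Whether a difference in cell composition produced this rise was not tested. All 43 genes of the S phase list were higher (median log2 fold change 0.51, camera adjusted p = 1.51e-15; adjusted p = 0.211 with an estimated correlation). Cyclin E1, CCNE1, rose from 48.5 ± 1.91 to 90.7 ± 4.01 CPM (SD, n = 2 each; 0.90, SE 0.057) and the helicase subunit MCM4 from 236 ± 3.68 to 386 ± 4.57 CPM (SD, n = 2 each; 0.71, SE 0.05). Of 38 G2/M and mitosis genes, 26 rose, 0 fell and 12 did not pass (27 higher adjusted over the list alone; median 0.17, camera adjusted p = 8.75e-06; adjusted p = 0.211 with an estimated correlation), including CDC20 (0.45, SE 0.048) and KIF20A (0.36, SE 0.051). Canonical histone genes, most of whose transcripts lack poly(A) tails, fell in 6 of 33, with 0 higher and 27 not past the threshold (median -0.23, camera adjusted p = 0.0388; adjusted p = 0.422 with an estimated correlation). Among all genes tested, 3908 of 16203 fell. The histone genes that fell included HIST1H2AC (-0.54, SE 0.061) and HIST1H4H (-0.73, SE 0.12). The histone call was lost without a count filter, in limma voom, and without the shallower control library or the deeper knockdown library (median -0.13 without the last; adjusted p over its alternatives 0.012 to 0.422).

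Messages of cytosolic ribosomal proteins and of the mitochondrial genome were higher. Of 66 cytosolic ribosomal protein genes, 62 rose, 0 fell and 4 did not pass (median log2 fold change 0.37, camera adjusted p = 2.31e-14; adjusted p = 0.211 with an estimated correlation), and together they took 3.73 ± 0.0205% of counts in the control and 5.05 ± 0.053% in the knockdown (SD, n = 2 each). RPL8 (0.57, SE 0.06) and RPS16 (0.52, SE 0.054) were examples. All 13 mitochondrially encoded mRNAs rose (median 0.62, camera adjusted p = 0.00107; adjusted p = 0.464 with an estimated correlation and, in fry, 0.126), from 2.87 ± 0.549% to 4.25 ± 0.34% of counts (SD, n = 2 each). MT-ND6 rose by 0.62 (SE 0.077) and MT-ND5 by 0.59 (SE 0.091) on the log2 scale. Without the deeper control library the median of these 13 mRNAs was 0.41.

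Genes of the amino acid and heme-regulated stress response under ATF4 rose in 18 of 32, with 5 lower and 9 not past the threshold (19 higher and 8 lower adjusted over the list alone; median log2 fold change 0.19, camera adjusted p = 0.0133; adjusted p = 0.267 with an estimated correlation). The serine synthesis enzyme PSAT1 rose from 60.1 ± 2.65 to 118 ± 0.82 CPM (SD, n = 2 each; 0.98, SE 0.053) and asparagine synthetase ASNS by 0.82 (SE 0.048) on the log2 scale, whereas PPP1R15A (-0.39, SE 0.05) and CEBPB (-0.48, SE 0.066) fell. The members that fell also included DDIT3, an effector of prolonged stress (-0.32, SE 0.056). Markers of other lineages fell in the same libraries (62 of 70), and cell composition was not tested as a cause of this rise. The ATF4 call was lost under the filter of 10 CPM (adjusted p = 0.0623; range over its alternatives 0.00484 to 0.267). Of 25 p53 target and apoptosis genes, 10 rose, 3 fell and 12 did not pass (median 0.06, from 0.068 to 0.114 with a library left out, camera adjusted p = 0.0645), with CCNG1 (0.48, SE 0.051) and FDXR higher and PMAIP1 (-0.39, SE 0.063) and GADD45A (-0.26, SE 0.049) lower. This list passed with library size alone, without a count filter, in limma voom and in fry (adjusted p over its alternatives 0.00213 to 0.267). Cholesterol synthesis genes were mixed, with 8 higher, 3 lower and 14 not past the threshold of 25 (median 0.07, from 0.032 to 0.104 with a library left out, camera adjusted p = 0.174). MVD (0.40, SE 0.055) and DHCR7 (0.58, SE 0.086) rose, and INSIG1 (-0.16, SE 0.048) fell. The INSIG1 call was lost with either knockdown library left out, with library size alone and without a count filter (adjusted p over its alternatives 0.00305 to 0.165).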

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

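The library size covariate, the block by column letter and the restriction to abundant genes were chosen after the data were examined. The planned block by replicate number could not be run as such, because the count columns carry the letters A and B rather than the labels' replicate numbers. A replicate block by column letter was run in its place and gave 3829 genes higher in NCOA4 kd and 4092 genes lower in NCOA4 kd, with every named gene and list keeping its call and direction. The differences between libraries A and B of the 2 groups correlated at 0.076 across genes, so the data do not show that the letters pair the libraries. The pseudocount alternative applied only to a table without counts and was not run. NCOA4 stayed lower in all 13 alternatives, with log2 fold changes from -1.17 to -1.09 and edgeR, DESeq2 or limma adjusted p from 4.41e-103 to 4.2e-07. Requiring a 2-fold change left 111 genes higher and 1148 lower, and counting only those with a mean log2 CPM of at least 5 left 1997 genes higher in NCOA4 kd and 1485 genes lower in NCOA4 kd. Fewer genes can pass in both by construction. Over the refits the 2-fold rises ran from 12 under the filter of 10 CPM to 229 without the deeper knockdown library and the 2-fold falls from 416 to 1203. The other alternatives gave counts within 1.5 times the main ones, from 2481 in DESeq2 to 4105 with library size alone for rises and from 2819 under the filter of 10 CPM to 4128 with the covariate for falls. Leaving out each library in turn gave 2923 to 3338 rises and 3343 to 3503 falls, with the lone library of a group assumed to vary like the others. Another scaling moved the median of all genes by at most 0.04 on the log2 scale. The number of lists passing was 16 to 20 across the refits, 22 in fry and 0 with an estimated correlation. The simulated shifted list was missed with an estimated correlation as well. Its genes were drawn independently, so that miss does not show which setting holds for the real lists. Of the 19 lists called, 14 kept their call and direction in all 13 refits. The first principal component held 75.8% of the variance over the most variable genes and 72.6% with library size alone. Of the 100 other named genes that were called, 92 kept call and direction in every alternative. Among the named genes and lists, signs that turned were those of values near 0. Among all 7463 called genes, as far as a refit tested them, 1 turned its sign without the shallower knockdown library and 0 in each other refit. The log2 fold change of the gene FTH1 was 0.002305 with library size alone and from -0.1501 to 0.06954 with a library left out, and that of FTL from -0.03414 to 0.1608. The list iron storage, uptake and export had a median of -0.0001636 under the filter of 10 CPM and of 0.03862 with a downward direction in fry. The list erythroid transcription factors turned to an upward direction in camera without a count filter (median -0.06367) and without the shallower knockdown library, with medians from -0.09988 to -0.066 when a library was left out. The cause of these turns was not tested. In the shallowest library 1 count was worth 0.0395 CPM, and the self-test recovered 34.7% of the smallest changes simulated, so many changes of that size were not detectable.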

Other observations

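All patterns below were noticed in these data first. Both tests of the lineage markers were chosen after the list medians and calls had been seen, and the gene families, single genes and pseudogenes were picked after their values were seen. When genes were grouped by the root of their symbol, 88 families with at least 15 tested members could be compared, and 20 passed camera at an adjusted p under 0.05 with the preset correlation, against 0 with an estimated correlation (lowest adjusted p = 0.622). A root is not a protein family, and several roots also hold antisense RNAs, pseudogenes or partner proteins. The roots of the mitochondrial ribosomal proteins rose alongside the cytosolic ones. Of 48 genes under MRPL, which include MRPL23-AS1 and MRPL45P2, 34 rose and 0 fell (median log2 fold change 0.27, camera adjusted p = 3.06e-06), as with MRPL3 (0.55, SE 0.053) and MRPL39 (0.65, SE 0.064), and of 29 genes under MRPS, 24 rose and 0 fell (median 0.29, camera adjusted p = 3.06e-06). Genes under NUP, mainly nucleoporins, rose in 16 of 20 with 0 lower (median 0.34, camera adjusted p = 0.000134), including NUP155 (0.55, SE 0.062) and NUP37 (0.50, SE 0.055). Genes under POLR, mainly RNA polymerase subunits, rose in 13 of 31 with 1 lower (median 0.19, camera adjusted p = 0.00258), led by POLR1E of polymerase I (0.67, SE 0.062), and genes under COX, subunits and assembly factors of cytochrome c oxidase with an antisense RNA, in 12 of 22 with 0 lower (median 0.21, camera adjusted p = 0.00407). The roots RPL, RPS, ZNF, RAD, EIF, TRMT, CEP, TAF and METTL also passed camera in the upward direction, although many of their members were not called, as in ZNF, where 129 of 480 rose and 31 fell, and EIF, where 25 of 59 rose and 4 fell.

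The other roots that passed went down. Phosphoinositide kinase genes and relatives under the root PIK fell in 11 of 16 with 1 higher (median log2 fold change -0.39, camera adjusted p = 0.00762), including PIK3CD, the leukocyte catalytic subunit (-1.08, SE 0.069), and PIK3R1 (-0.78, SE 0.06). Genes under RAB, small GTPases together with effectors, regulators, antisense RNAs and a pseudogene, fell in 25 of 65 with 9 higher (median -0.15, camera adjusted p = 0.00762), genes under GPR in 19 of 46 with 3 higher (median -0.38, camera adjusted p = 0.0175), as with GPR34 (-1.32, SE 0.099), and genes under DUSP, mainly dual-specificity phosphatases, in 10 of 20 with 0 higher (median -0.23, camera adjusted p = 0.0454), as with DUSP6 (-1.30, SE 0.082) and DUSP4 (-1.58, SE 0.18), both known as feedback targets of ERK signalling. The root ARHGEF fell in 11 of 16 with 1 higher (camera adjusted p = 0.00762) and KLF in 8 of 15 with 1 higher (camera adjusted p = 0.0461).

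The fall of other-lineage markers was weighed against 2 explanations. The first was a trend of fold change with expression level. The pooled median of the 70 markers was -1.22 (quartiles -1.41 and -1.02). The middle 95% of 10000 random lists matched on mean expression ran from -0.10 to 0.11, and 0 percent of them were as low. Other genes of like mean expression thus did not share the fall. That is all this test shows, because the marker medians were known when it was chosen. A smaller share of cells of other lineages in the knockdown cultures would lower their abundant transcripts together, and 18 of the 18 most abundant markers fell (100%, median -1.23), from CLC (-1.23) and HDC (-1.26) to RNASE2 (-1.01), so this explanation stays open as a hypothesis; with 62 of 70 markers already known to fall, the test had little room to come out otherwise. LTBP1 (-0.38) and KIT (-0.65) fell less, CYBB (0.05, SE 0.087) and LTF (0.10, SE 0.11) did not pass, and 3 of the 70 markers are also in another list; erythroid cells express some of these genes themselves. A direct effect of the knockdown on these genes within erythroid cells was not tested, and no sort is mentioned in the labels.

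The rise of ribosomal protein mRNAs was weighed against transcript length and GC content, and that of mitochondrial mRNAs against dependence on 1 knockdown library. After a correction for transcript length the ribosomal protein median was 0.38 (95% interval from a bootstrap over genes 0.35 to 0.42), against 0.37 before. After one for GC content it was 0.39 (0.36 to 0.41), and all 66 genes were annotated. The intervals resample these genes as if independent and hold the libraries fixed, so they do not measure the spread between libraries. Both properties were those of the longest annotated transcript of each gene (median 1864 bases for the ribosomal protein genes), which need not be the one expressed. The length correction therefore cannot exclude an effect of short transcripts. The trend with the GC content of these transcripts did not account for the ribosomal protein rise. Neither correction was made for the mitochondrial mRNAs. The mitochondrial median was 0.53 at its lowest when either knockdown library was left out (0.70 at its highest), so it does not rest on 1 of them, while it was 0.41 without the deeper control library. A response to the knockdown may remain, as a hypothesis found and tested on the same data, and a difference in cell stage or cell composition was not tested.

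The excess of large falls was weighed against scaling and low counts. Falls made up 91.2% of the 2-fold calls, and 96.6% (142 of 147) among genes with a mean log2 CPM of at least 5. The latter argues against low counts as the whole cause. Under each other scaling falls made up at least 88.6% of the 2-fold calls. Those scalings moved the median of all genes by at most 0.04 on the log2 scale. A shift that small could hardly change that share, so scaling was not put to a real test. Without the deeper knockdown library the share was 83.0%. Whether the lower other-lineage transcripts account for most of these falls was not tested, because the lists hold only 70 such genes.

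The shallower knockdown library stood apart in both directions in some copies of mitochondrial or ribosomal protein sequence. MTATP8P1 was at 16.9 CPM there and at 3.29, 2.23 and 1.14 CPM in the deeper knockdown and the deeper and shallower control libraries. In the same order MTRNR2L9 was at 53.5 against 6.43, 6.98 and 9.08 CPM, and RPL13P12 at 40.0 against 12.6, 8.91 and 10.8 CPM. Other copies were low in it, such as RPS2P46 at 7.61 against 62.7, 42.3 and 42.8 CPM and RPS2P5 at 4.21 against 37.1, 23.6 and 21.0 CPM. These are examples, and no count of such copies was made. Alpha-globin (HBA1 and HBA2) took 1.36 ± 0.327% of counts in the control against 10.5 ± 0.679% for HBB (SD, n = 2 each). The largest single fall, that of NETO2, was 38.8-fold, against 2.19-fold for NCOA4 itself. Whether this fall or others came from an off-target effect of the hairpin was not tested.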
